A study of Homo sapiens with 4 samples.

How the data were processed

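RNA was sequenced from MCF7 and T47D, 2 established human breast cancer cell lines that carry the estrogen receptor. Each line gave 1 control library at day 0 and 1 library after palbociclib at 1 µM until day 5, so there were 4 libraries and 1 library per group. Palbociclib is an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. Per the labels' protocols, MCF7 was kept in DMEM and T47D in an RPMI medium, and libraries were made from total RNA with a kit for messenger RNA. Groups were taken from the sample titles, since the treatment tag of every sample reads palbociclib, the day 0 samples included. The columns of the deposited tables carry the name of the line alone or with a suffix for the drug, and a column with the line alone was taken as the control library of that line. No label says that the libraries of the 2 lines came from more than 1 culture each.

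The submitters' processing notes name the read trimmer Trimmomatic 0.38, the aligner HISAT2 2.1.0, the counting tool featureCounts 2.0.0 and the GRCh38 build. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited read count tables, per the file headers, hold whole numbers for 58884 Ensembl genes in each line. The authors also deposited TPM values, which sum to the same value in each library. The FPKM values the authors deposited equal the count divided by the library's total count and a whole-number gene length. That length was the exon union of GENCODE 29 for 25165 of 33321 genes that could be compared (75.5%). The authors' edgeR-normalized values are CPM of an effective library size, as the count divided by the value was constant within each library. Those tables hold 14515 genes for MCF7 and 14468 for T47D, and the filter behind them is not given in the sources used here. Of the gene IDs, 58472 had a symbol in the gene name table and 58611 were found in GENCODE 29, from which gene types and GRCh38 coordinates were taken. Each of the 16 columns of values belonged to a library, and no row of the count tables lacked a gene name.

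Reads shared between genes limit some values. Without a known strand setting, reads of overlapping genes cannot be assigned with certainty. More than 10% of the exon length was shared with a gene of over 10 reads for CDK4 (TSPAN31, 43.2%), CTSD (a gene on the same strand, 41.7%), CCNE2 (INTS8, 37.0%), USP37 (VIL1, 32.8%), WIPI1 (ARSG, 24.3%) and KCNK15 (RIMS4, 19.5%). The same held for OSGIN1 (13.9%), CYP1B1 (CYP1B1-AS1, 11.3%), CDH3 (CDH3-AS1, 11.1%) and CCND1 (LTO1, 10.3%). Genes whose neighbour had fewer reads are not in this list. Among them are RPS10 (RPS10-NUDT3, 39.4%) and COX8A (34.5%), each with the neighbour on the same strand. How reads on such shared exons were counted is not known. PCDHGB2 shares 45.7% of its exon length with PCDHGA1 on the same strand. The pseudogenes of RPS10 held 289 reads over the 4 libraries and RPS10 itself 235, so its value is uncertain. Pseudogenes of UBE2C held 174 reads against 4167 for the gene, those of UBE2S held 28 against 5804, and none is annotated for UBE2T.

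The comparison across both lines used edgeR 4.0.16 in R 4.3.3 on the deposited counts: the quasi-likelihood F test with the cell line as a block, TMM scaling and the edgeR filter on low counts. The labels pair the libraries by cell line. This fit has 1 residual degree of freedom, and the test borrows the spread between genes (prior degrees of freedom 23.4, biological coefficient of variation 0.13). P-values were adjusted by the Benjamini-Hochberg method over the 16641 genes tested, at a threshold of 0.05. The SE of a log2 fold is its absolute value divided by the square root of the F statistic. The verbs rose and fell are used for genes past that threshold. The p-values set the size of the response against a spread borrowed mostly from other genes, and only partly against the gene's own difference between the lines. A gene whose lines disagree can therefore pass, and 56 called genes had opposite signs in the lines. The p-values cover neither cultures nor days. Within a line there was 1 library against 1, so values are given with no p-value. They are log2 folds of TMM-scaled CPM with a prior count of 2, and genes with an absolute log2 fold of at least 1 were counted as higher or lower. Intervals of a line's fold are exact Clopper-Pearson 95% intervals from the 2 counts, and like the floor of 3 counts for a gene without reads they cover counting error only. The floor replaces a count of 0 and leaves out the error of the other count, so a bound from it can lie beyond the interval's limit. That floor lay between 0.173 and 0.183 CPM.

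Before the data were examined, 34 gene lists with 906 entries were written down, of which 2 genes had no match. For each list the members called in each direction were counted, over all genes tested and adjusted over the list alone. The median fold of a list in a line was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these libraries and is not a test. UBE2C, UBE2S and UBE2T are named in the series title, so the study chose them, possibly on these samples.

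The genes named below follow a rule fixed before the data were examined, with the exceptions given at the end of this paragraph. It takes UBE2C, UBE2S and UBE2T. It takes the 6 called protein-coding genes in each direction whose smaller line fold was largest, with a mean of at least 5 CPM. From each list it takes up to 4 members with the largest mean fold, along with MKI67, CCNB1, CCND1, CCNE2, CDK4, CDK6, RB1, CDKN1A, ESR1 and PGR. Within each line it takes the 5 highest and 5 lowest protein-coding genes of at least 5 CPM, and up to 4 genes for each way in which the lines went in opposite directions. CDKN2A, deleted in MCF7, serves as a check of the line labels. The lymphocyte genes, the NRF2 and aryl hydrocarbon receptor targets and the genes that open the other observations were chosen after their values were seen.

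The fit was tested on simulated counts for 16260 genes with the real means and library sizes, of which 198 were changed. Both lines were given the same change, and the spread of each gene followed the dispersion trend of the fit itself. Lines that respond differently were not simulated. It recovered 72% of the genes changed by 2-fold and 100% of those changed by 4-fold, and 14 of its 184 calls were false (7.61%). With no gene changed it made 0 calls in edgeR, and 4.58% of genes had an unadjusted p under 0.05. A list shifted on purpose lay at percentile 100 and a list left as it was at 25.2. In separate Poisson counts with a single pair of means and libraries of equal size, 95.5% of the counting intervals held the true fold.

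Alternatives were other scalings (size factors of DESeq2 1.42.0, upper quartile, total counts, TMM within a line), other filters, protein-coding genes alone, the robust option, no line block and the DESeq2 Wald test. The authors' normalized values with limma 3.58.1 (pseudocount 1 on the log2 scale across both lines, 2 within a line), their TPM and FPKM (pseudocount 1), prior counts of 0.5 and 5, and a counting interval beyond 1.5-fold were also run. An alternative without lymphocyte genes was added after the data were seen. Nothing was left out of the main comparison except genes below the edgeR filter.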

Results

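Gene expression was measured by RNA sequencing in MCF7 and T47D before and after palbociclib, an inhibitor of CDK4 and CDK6, kinases that drive entry into S phase by phosphorylating RB1. The total count was 15923985 in the MCF7 control library, 17727316 in the MCF7 palbociclib library, 16052271 in the T47D control library and 17491850 in the T47D palbociclib library. Protein-coding genes took between 96.5% and 97.1% of the counts, mitochondrial genes between 2.57% and 2.98%, and the 10 most abundant genes between 4.63% and 5.76%. CDKN2A, which encodes p16 and is deleted in MCF7, had 20 and 15 reads in the MCF7 libraries and 332 and 326 in the T47D libraries. There were no replicates within a line. The control was taken at day 0 and the treated culture at day 5, so each difference holds the drug and the days in culture together.

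Genes of T and B lymphocytes had reads in all 4 libraries, in lines of epithelial origin. TRAC, the constant gene of the T-cell receptor alpha chain, had 5913, 6096, 3926 and 3801 reads in the MCF7 control, MCF7 palbociclib, T47D control and T47D palbociclib libraries. IGKC, the constant gene of the immunoglobulin kappa chain, had 29973, 32034, 20451 and 19267 reads in the same order, and CD3E had 2593, 2862, 1808 and 1604. The 40 listed lymphocyte genes took 0.855%, 0.822%, 0.58% and 0.507% of the counts. Their reads stood at a nearly fixed ratio between libraries: over the 30 genes with a mean of at least 100 reads, the log2 ratio of the MCF7 to the T47D control, as shares of the total counts, had a median of 0.55 and an SD of 0.09. Over all tested genes of that level or above, the SD was 1.75. CD53, LAPTM5 and IL2RG, which lymphocytes also express, had between 0 and 7 reads in each library, while ITGB2, SELL, CXCR4 and CCR7 of the same list of 17 genes had between 297 and 4172. The median log2 fold of the 30 genes, palbociclib over control with TMM, was 0.04 in MCF7 and -0.03 in T47D. As shares of the total counts, the median log2 ratio of control over palbociclib was 0.03 in MCF7, the opposite direction, and 0.18 in T47D. The list of blood and endothelial markers had 6 measured members, CD3D, CD3E, PTPRC and MS4A1 among them, and 0 passed the edgeR test in either direction, also adjusted over the list alone (0 at an unadjusted p under 0.05, 0 in the DESeq2 Wald test). Which other genes received such reads is unknown.

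**Figure D1:**
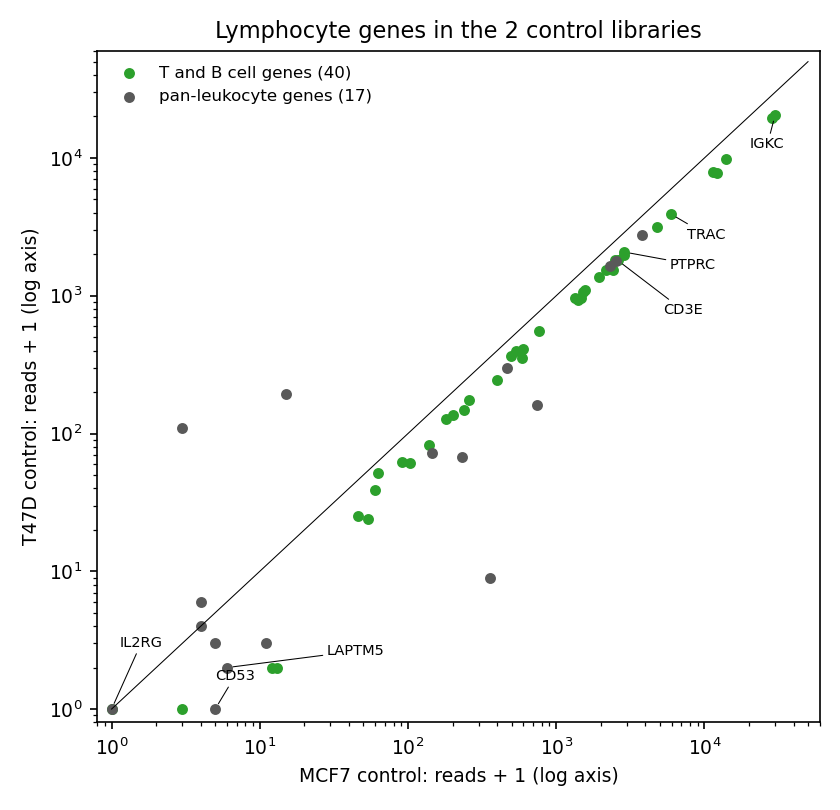
Reads of 40 T and B cell genes and 17 pan-leukocyte genes, each plus 1, in the MCF7 control library (horizontal) and the T47D control library (vertical), on log axes with the line of equal reads. Each point is a gene, and the T and B cell genes with a mean of at least 100 reads lie along a line parallel to the diagonal. Their median log2 ratio, taken as shares of the total counts, was 0.55.

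The series title names the ubiquitin-conjugating enzymes UBE2C, UBE2S and UBE2T, and the comparison of palbociclib with control across both lines addresses their expression. UBE2C, which works with the anaphase-promoting complex in mitosis, fell by 2.05 on the log2 scale (SE 0.15, 2 lines, adjusted p = 6.3e-10 in the edgeR quasi-likelihood test). UBE2T, the conjugating enzyme of the Fanconi anaemia pathway, fell by 1.85 (SE 0.17, adjusted p = 2.6e-08), and UBE2S, which extends ubiquitin chains on substrates of the anaphase-promoting complex, fell by 1.65 (SE 0.15, adjusted p = 1.9e-08). As folds, expression under palbociclib was 0.242, 0.277 and 0.32 of the control for UBE2C, UBE2T and UBE2S. All 3 were lower in 2 of 2 lines.

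UBE2C (ENSG00000175063) lies on chromosome 20 from 45812576 to 45816957 on the plus strand of GRCh38, a protein-coding gene in the annotation, and its reads went from 1384 to 360 in MCF7 and from 1964 to 459 in T47D. UBE2S (ENSG00000108106), on chromosome 19 from 55399745 to 55407777 on the minus strand, went from 2573 to 1005 reads and from 1753 to 473. UBE2T (ENSG00000077152), on chromosome 1 from 202331657 to 202341980 on the minus strand, went from 862 to 277 reads and from 1024 to 254. The log2 fold in MCF7 was -2.02 for UBE2C (95% counting interval -2.20 to -1.86), -1.44 for UBE2S (-1.55 to -1.33) and -1.71 for UBE2T (-1.92 to -1.52). In T47D it was -2.06 for UBE2C (-2.22 to -1.92), -1.86 for UBE2S (-2.01 to -1.71) and -1.97 for UBE2T (-2.19 to -1.78). With the reads of their pseudogenes added, the line fold nearest to 0 was -1.43. All 6 line folds lay inside the central 95% of the 52 genes of G2/M and mitosis in the same line, which ran from -2.63 to -0.71 in MCF7 and from -3.67 to -0.32 in T47D. Without the cell line as a block, none of the 3 passed, with an adjusted p of 1 in edgeR.

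Of the 38 conjugating enzymes measured, 3 rose, 3 fell and 32 did not pass, with 3 and 3 adjusted over the list alone. The 3 that fell are those of the series title, which form a list of their own with 3 of 3 down, 3 also adjusted over the list alone. Since the study chose them, this count is not independent evidence. UBE2H rose by 0.77 (SE 0.14, adjusted p = 0.00025), UBE2J1, an enzyme of the endoplasmic reticulum, by 0.62 (SE 0.15, adjusted p = 0.0064) and UBE2E2 by 0.51 (SE 0.16, adjusted p = 0.035). UBE2E2 did not pass with upper-quartile factors, total counts, a mean of at least 5 CPM or the DESeq2 Wald test, and none of these 3 passed in limma on the authors' values. The 35 enzymes other than those of the series title had a median log2 fold of -0.06 in MCF7, between -0.37 and 0.87, and of 0.14 in T47D, between -0.76 and 0.90.

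**Figure D2:**
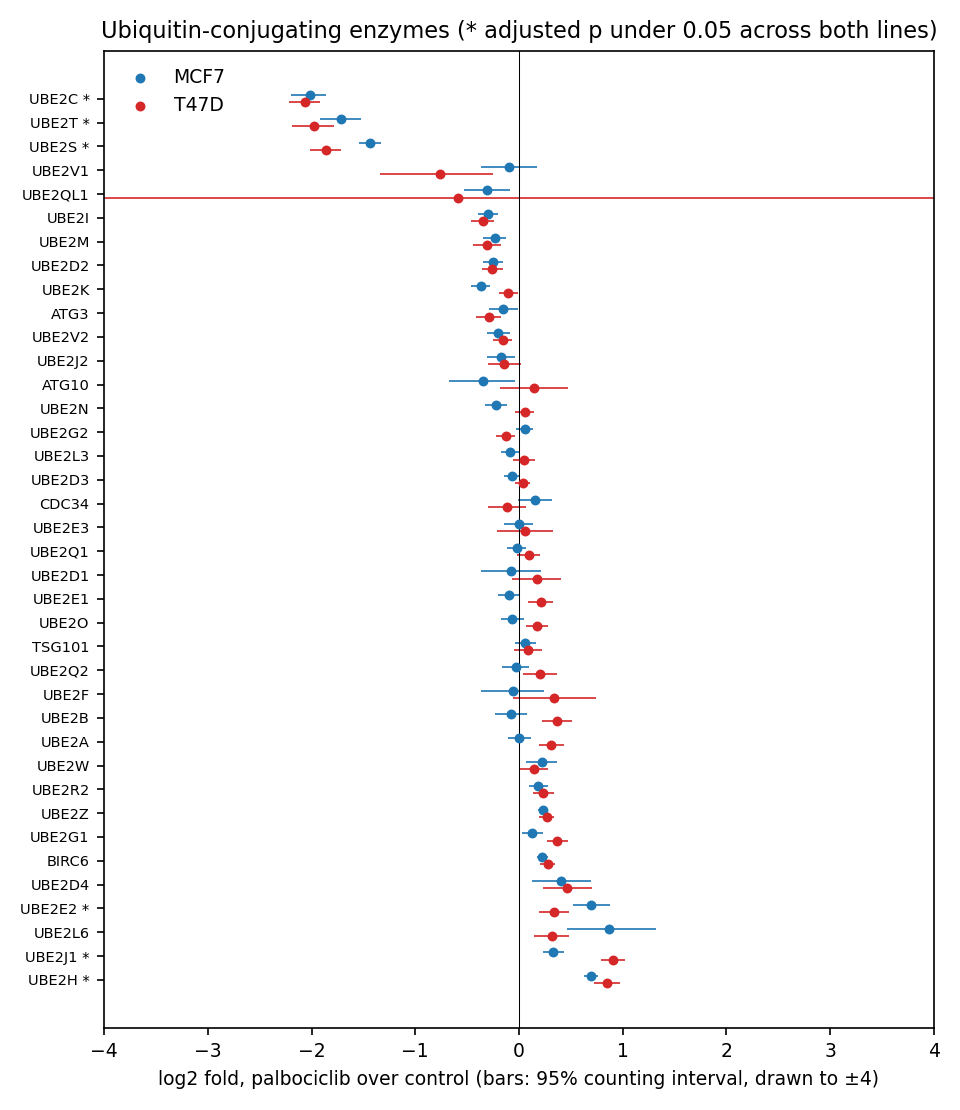
Log2 fold of palbociclib over control for 38 ubiquitin-conjugating enzymes in MCF7 (blue) and T47D (red), with 1 library per condition in each line and bars for the 95% counting interval, drawn to -4 and 4. UBE2C, UBE2T and UBE2S lie between -2.06 and -1.44, and stars mark the 6 enzymes with an adjusted p under 0.05 in edgeR across both lines.

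Ligases of the ubiquitin system were covered by 3 lists. Of 16 cell-cycle ligases and adaptors, 1 rose, 10 fell and 5 did not pass, with 1 and 12 adjusted over the list alone, and the list median was -1.21 in MCF7 and -0.75 in T47D. The log2 fold was -2.62 (SE 0.28) for FBXO5, an inhibitor of the anaphase-promoting complex, -2.42 (SE 0.16) for UHRF1, -1.82 (SE 0.17) for DTL, a substrate receptor active in S phase, and -1.69 (SE 0.17) for BARD1, the partner of BRCA1. Of the 16 genes of the anaphase-promoting complex, 0 rose and 1 fell, with 0 and 1 adjusted over the list alone: the activator CDC20 fell by 1.37 (SE 0.16, adjusted p = 8.2e-07). In the core of the cullin ligases, 3 of 20 rose and 0 fell, with 3 and 0 adjusted over the list alone. BTRC rose by 0.62 (SE 0.16), FBXW11 by 0.59 (SE 0.15) and DDB1 by 0.38 (SE 0.13), the last of which did not pass under the 3 other scalings.

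Few genes of the proteasome passed the test. Of 32 genes of the 26S proteasome, 0 rose, 2 fell and 30 did not pass, with 0 and 2 adjusted over the list alone. PSMC3, an ATPase of the base, fell by 0.68 (SE 0.13, adjusted p = 0.0007) and PSMB6, a catalytic subunit, fell by 0.48 (SE 0.15, adjusted p = 0.024). Neither passed in limma on the authors' values, and PSMB6 did not in the DESeq2 Wald test. With total counts in place of TMM, 5 of the 32 fell. The list median was -0.22 in MCF7, at percentile 0.01 of matched random lists, and -0.03 in T47D, at percentile 1.27, where matched lists had a median of 0.13. Of the 5 genes of the immunoproteasome and its activator, 0 passed in either direction in edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, 0 in the DESeq2 Wald test), and the medians were 0.26 and -0.35. With total counts 1 of the 5 fell. Of 32 deubiquitinases, 2 rose and 3 fell, with the same counts adjusted over the list alone. USP1, which removes ubiquitin from FANCD2 and PCNA, fell by 1.45 (SE 0.15, adjusted p = 9.2e-08). USP37 fell by 0.85 (SE 0.17) and USP13 fell by 0.50 (SE 0.15), while USP9X rose by 0.42 (SE 0.13) and USP20 by 0.45 (SE 0.16). USP20 did not pass under the 3 other scalings, USP9X did not with upper-quartile factors or total counts, and USP13 did not with DESeq2 size factors, upper-quartile factors or a mean of at least 5 CPM. None of USP13, USP20 and USP9X passed in limma on the authors' values, and USP13 and USP20 did not in the DESeq2 Wald test.

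Across all 16641 genes tested, 1500 rose and 1015 fell, 205 and 309 of them by at least 2-fold in both lines. With total counts in place of TMM, the split was 906 up and 1373 down, or 39.8% up against 59.6%. Of the 2515 called genes, 2459 had the same sign in both lines and 56 had opposite signs. With the lymphocyte genes left out, an alternative added after the data were seen, 1534 rose and 1050 fell, and 2512 of the calls were shared. Among the named genes with an adjusted p in the setting, 27 calls were lost in the DESeq2 Wald test and 52 in limma on the authors' values. Some called genes had none, such as CXCL8 in both. With the line block left out, so that the spread between the lines enters the error, 0 genes passed in edgeR (329 at an unadjusted p under 0.05).

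CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, led the genes that rose by the naming rule, with a rise of 3.46 on the log2 scale (SE 0.19, adjusted p = 1.4e-11). Its reads went from 179 to 1595 in MCF7 (8.33-fold) and from 100 to 1461 in T47D (14.6-fold). BCAS1 rose by 2.31 (SE 0.15), CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, by 2.18 (SE 0.20), SYNPO, an actin-binding protein, by 2.16 (SE 0.24) and CLIC6 by 2.34 (SE 0.24). HMGCS2, the mitochondrial enzyme of ketone body synthesis, rose by 2.01 (SE 0.25), with 2 and 24 reads in MCF7 and 370 and 1332 in T47D. The genes that fell by the same rule had log2 folds of -3.80 (SE 0.34) for PIF1, a DNA helicase, -3.33 (SE 0.24) for E2F7, a repressor of E2F targets, and -3.22 (SE 0.26) for AURKB, a mitotic kinase. KIF20A, a mitotic kinesin, fell by 2.98 (SE 0.18), HMGB2, a chromatin protein, fell by 2.91 (SE 0.16) and PTTG1, the securin of sister chromatids, fell by 2.66 (SE 0.18). The adjusted p-values of these 12 genes ran from 1.1e-11 to 2.2e-06.

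In GRCh38, CYP1A1 (ENSG00000140465) lies on the minus strand of chromosome 15 from 74719542 to 74725610, BCAS1 on chromosome 20 from 53936777 to 54070594, CDKN2B on chromosome 9 from 22002903 to 22009363 and HMGCS2 on chromosome 1 from 119747996 to 119768905. Of the genes that fell, PIF1 lies on chromosome 15 from 64815632 to 64825668, E2F7 on chromosome 12 from 77021247 to 77065580, AURKB on chromosome 17 from 8204733 to 8210600 and HMGB2 on chromosome 4 from 173331695 to 173335125. All 8 are protein-coding genes on the minus strand.

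**Figure D3:**
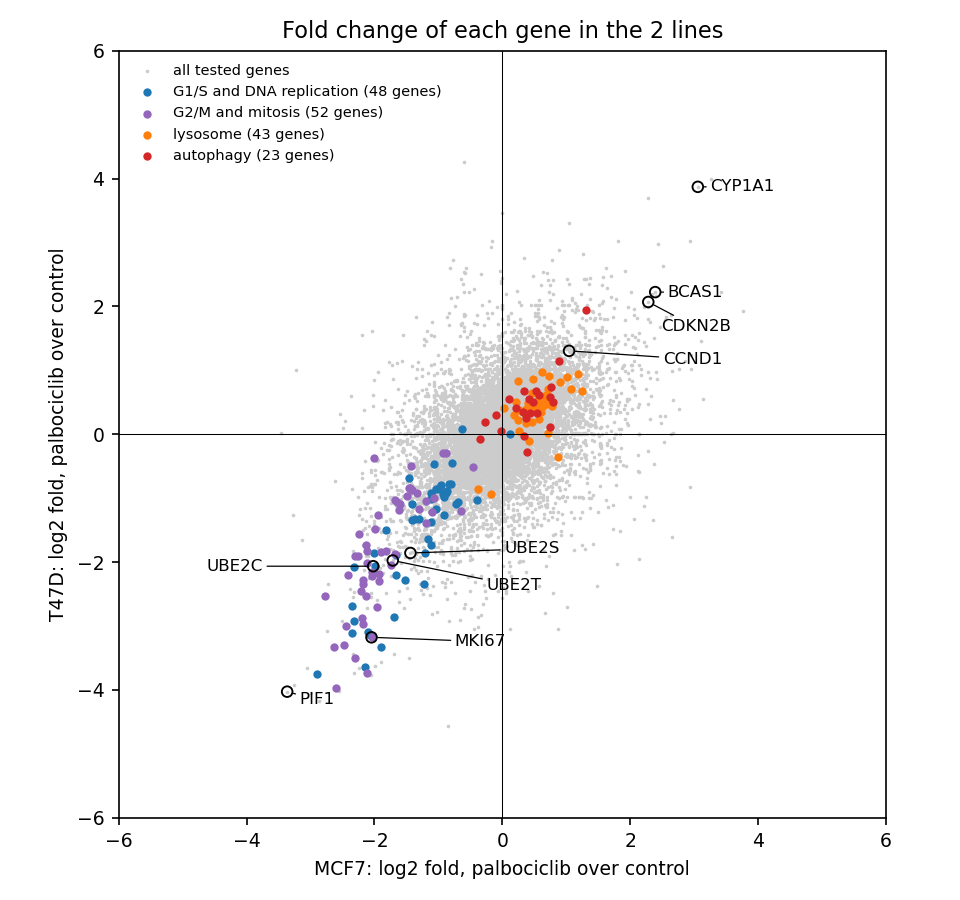
Log2 fold of palbociclib over control in MCF7 (horizontal) and T47D (vertical), with 1 library per condition in each line; grey points are the 16641 tested genes, coloured points 4 gene lists and rings 9 named genes. The 52 genes of G2/M and mitosis lie below 0 in both lines, and CYP1A1 lies at 3.06 and 3.87.

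The cell cycle was covered by lists of its phases and of DNA repair. Of 52 genes of G2/M and mitosis, 52 fell, also adjusted over the list alone, with a median log2 fold of -1.95 in MCF7 and -1.83 in T47D. Of 48 genes of G1/S and DNA replication, 0 rose, 45 fell and 3 did not pass, with 46 down adjusted over the list alone, and the medians were -1.14 and -1.29. MKI67, a marker of proliferating cells, fell by 2.61 (SE 0.18), from 10065 to 2580 reads in MCF7 and from 9412 to 1019 in T47D, and CCNB1, the mitotic cyclin B1, fell by 1.30 (SE 0.14). The log2 fold was -2.89 (SE 0.23) for MYBL2, a transcription factor of the cell cycle, -2.90 (SE 0.21) for CCNA2, cyclin A2, -2.87 (SE 0.22) for RRM2, a subunit of ribonucleotide reductase, -2.71 (SE 0.24) for E2F8 and -2.62 (SE 0.20) for E2F2. MKI67, MYBL2 and RRM2 did not pass with the robust option. CCNE2, cyclin E2, whose exons overlap those of INTS8, fell by 2.26 (SE 0.23). Of 30 genes of the Fanconi anaemia and homologous recombination list, 0 rose and 20 fell, with 24 down adjusted over the list alone, among them EXO1 with a log2 fold of -2.01 (SE 0.22), HELLS with -1.77 (SE 0.17), BLM with -1.73 (SE 0.20) and RAD51AP1 with -1.67 (SE 0.25).

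Of 20 regulators of G1, 5 rose, 6 fell and 9 did not pass, with 5 and 8 adjusted over the list alone. The list median was 0.02 in MCF7, at percentile 56.4, and -0.20 in T47D, at percentile 0.41. CCND1, cyclin D1, rose by 1.17 (SE 0.13, adjusted p = 2.1e-07), and CDK6, a target of the drug, rose by 1.48 (SE 0.19, adjusted p = 2.4e-06). CDK4, the other target, fell by 0.48 (SE 0.14, adjusted p = 0.02), with exons that overlap those of TSPAN31, and did not pass in the DESeq2 Wald test or in limma on the authors' values. CDKN2C, the p18 inhibitor of the same kinases, fell by 2.42 (SE 0.21), and RBL1, the RB1 relative p107, fell by 1.31 (SE 0.18). RB1 had a log2 fold of -0.32 (SE 0.14, adjusted p = 0.13) and passed with total counts (-0.43). CDKN1A, which encodes p21, had 0.01 in MCF7 and -1.02 in T47D (adjusted p = 0.059), and passed without a filter, with protein-coding genes only and without the lymphocyte genes. Of 28 targets of p53, 4 rose and 6 fell, with 4 and 7 adjusted over the list alone. The list median was -0.08 in MCF7, at percentile 14.6, and -0.14 in T47D, at percentile 0.75. TP53INP1 rose by 1.23 (SE 0.14), while DDB2, a DNA damage sensor, fell by 1.30 (SE 0.16), AEN fell by 0.86 (SE 0.17) and TP53I3 fell by 0.95 (SE 0.20), the last with -0.17 in MCF7 and -1.49 in T47D. Of 15 histone genes with polyadenylated transcripts, 3 rose and 2 fell, with the same counts adjusted over the list alone: H2BC4 rose by 0.95 and H4C8 by 0.74, while the linker histone H1-0 fell by 1.02 and H3-3B fell by 0.75.

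The lists of the lysosome and of autophagy had medians above 0 in both lines. Of 43 lysosomal genes, 26 rose, 1 fell and 16 did not pass, with 32 and 2 adjusted over the list alone, and the median of 0.47 in MCF7 and 0.45 in T47D lay above that of all 10000 matched random lists in each line. ARSA, arylsulfatase A, rose by 1.07 (SE 0.20), the lysosomal protease CTSD, which overlaps another gene on its strand, by 0.95 (SE 0.12), the calcium channel MCOLN1 by 0.95 (SE 0.24) and GNS by 0.90 (SE 0.13). MCOLN1 did not pass in the DESeq2 Wald test, and neither MCOLN1 nor GNS did in limma on the authors' values. Of 23 autophagy genes, 10 rose, 0 fell and 13 did not pass, with 14 and 0 adjusted over the list alone, and the medians were 0.42 and 0.41, at percentiles 100 and 99.9. GABARAPL1 rose by 1.73 (SE 0.24), WIPI1 by 1.03 (SE 0.15), MAP1LC3B by 0.75 (SE 0.14) and the initiating kinase ULK1 by 0.66 (SE 0.13). Neither MAP1LC3B nor ULK1 passed in limma on the authors' values.

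Of 24 genes of cholesterol synthesis, 2 rose and 5 fell, with 2 and 6 adjusted over the list alone. The list median was -0.16 in MCF7, at percentile 1.37, and -0.18 in T47D, at percentile 0.14. ACAT2 fell by 1.41 (SE 0.18), EBP fell by 0.87 (SE 0.20) and STARD4 fell by 0.85 (SE 0.29, adjusted p = 0.049), and TM7SF2 rose by 0.73 (SE 0.14). STARD4 did not pass with DESeq2 size factors or upper-quartile factors, and 3 of the 24 then fell. Of 25 genes of the unfolded protein and integrated stress responses, 4 rose and 3 fell, with 6 and 4 adjusted over the list alone. DDIT4 rose by 1.46 (SE 0.21) and the chaperone DNAJB9 by 1.09 (SE 0.17), while the serine synthesis enzymes PHGDH and PSAT1 had log2 folds of -1.82 (SE 0.18) and -1.30 (SE 0.31), both past the threshold. PSAT1 had a log2 fold of -0.07 on 13 and 13 reads in MCF7. Of 23 hypoxia genes, 7 rose and 1 fell, the same as adjusted over the list alone: ANGPTL4 rose by 1.29 (SE 0.24), NDRG1 by 1.26 (SE 0.20) and EGLN3 by 1.05 (SE 0.22), and ENO2, neuronal enolase, fell by 1.19 (SE 0.24). Of 19 glycolysis genes, 2 rose and 3 fell, with 2 and 4 adjusted over the list alone. The glucose transporter SLC2A1 rose by 0.71 (SE 0.15), PFKP fell by 0.86 (SE 0.19) and the lactate transporter SLC16A3 fell by 0.72 (SE 0.21). PFKP did not pass with upper-quartile factors, and 5 of the 19 fell with total counts.

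Few genes of oxidative phosphorylation and translation passed the test. Of 42 nuclear genes of oxidative phosphorylation, 0 rose and 1 fell, COX8A with a log2 fold of -0.49 (SE 0.15), and none passed in edgeR adjusted over the list alone (6 at an unadjusted p under 0.05). COX8A shares 34.5% of its exon length with another gene on its strand. Of 74 cytosolic ribosomal proteins, 0 rose and 1 fell, RPS10 with -1.20 (SE 0.35), a gene whose reads are shared with its pseudogenes, and none passed adjusted over the list alone (6 at an unadjusted p under 0.05). RPS10 also shares 39.4% of its exon length with RPS10-NUDT3 on the same strand. With TMM, the oxidative phosphorylation median was 0.01 in MCF7, at percentile 38.9, and -0.08 in T47D, at percentile 0.39. That of the ribosomal proteins was 0.09 in MCF7, at percentile 58.9, and -0.08 in T47D, at percentile 0. With total counts, 4 fell in each of these 2 lists. Of 30 ribosome biogenesis genes, 0 rose and 5 fell, with 0 and 6 adjusted over the list alone. The list median was -0.08 in MCF7, at percentile 7.67, and -0.18 in T47D, at percentile 0.03. The nucleolar methyltransferase FBL fell by 0.92 (SE 0.15), DKC1 fell by 0.49 (SE 0.15) and NOP56 fell by 0.48 (SE 0.15). With DESeq2 size factors 1 of the 30 fell and with upper-quartile factors 2, NOP56 in neither. Of 13 mitochondrial messenger RNAs, 1 rose, MT-CO1 by 0.36 (SE 0.12, adjusted p = 0.043), and none passed adjusted over the list alone (2 at an unadjusted p under 0.05). MT-CO1 did not pass under the 3 other scalings. The median of the mitochondrial list lay at percentile 33.0 in MCF7 and 35.0 in T47D.

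Secreted factors and genes that respond to YAP and serum were covered by 2 lists. Of 21 measured genes of the senescence-associated secretory list, 8 rose, 1 fell and 12 did not pass, the same as adjusted over the list alone, with medians of 0.53 and 0.45 at percentiles 100 and 99.9; with upper-quartile factors or total counts 5 rose. The protease PLAU rose by 1.82 (SE 0.57), IGFBP3 by 1.92 (SE 0.32) and INHBA by 1.74 (SE 0.36), with at most 15 reads in a T47D library for each, and PLAU did not pass with those scalings. CXCL8, the chemokine interleukin-8, fell by 3.10 (SE 0.58), a call from MCF7 alone, where it went from 175 to 15 reads, with 3 and 3 reads in T47D. Of 24 genes of the YAP and serum response, which varies with culture density, 8 rose and 0 fell, with 9 and 0 adjusted over the list alone, and 5 rose with upper-quartile factors or total counts. TGFB2 rose by 2.37 (SE 0.39) and CRIM1 by 1.05 (SE 0.14), while ANKRD1 passed with log2 folds of 2.37 in MCF7 and -0.47, on 5 and 3 reads, in T47D and under none of the 3 other scalings.

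Of 34 interferon response genes, 5 rose, 2 fell and 27 did not pass, with 8 and 2 adjusted over the list alone, and the medians of 0.27 and 0.07 lay at percentiles 99.6 and 64.9. With total counts the T47D median was -0.08 and 3 genes rose. SAMD9 rose by 1.67 (SE 0.36) and HERC5 fell by 1.74 (SE 0.47). Of 18 genes of class I antigen presentation, 5 rose and 0 fell, the same as adjusted over the list alone, and 3 rose with total counts. TAPBP, tapasin, rose by 0.63 (SE 0.13), the aminopeptidase ERAP1 by 0.75 (SE 0.16) and HLA-F by 0.92 (SE 0.31), which did not pass under the 3 other scalings. Lymphocytes express genes of both lists, and the lymphocyte genes took 0.855% and 0.822% of the counts in MCF7 and 0.58% and 0.507% in T47D, control before palbociclib.

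Of 30 estrogen response genes, 6 rose and 6 fell, with 7 and 8 adjusted over the list alone. The list median was 0.11 in MCF7, at percentile 80.1, and -0.21 in T47D, at percentile 0.01, where matched lists had a median of 0.11. ESR1, the estrogen receptor, fell by 0.53 (SE 0.13, adjusted p = 0.0052), but not in limma on the authors' values. KCNK15 rose by 1.58 (SE 0.25) and IGFBP5 by 1.18 (SE 0.15), the latter from 45434 to 135558 reads in T47D, and CXCL12 fell by 1.15 (SE 0.14). PGR, the progesterone receptor, had log2 folds of -0.56 in MCF7 and 0.09 in T47D (adjusted p = 0.3), the latter -0.07 with total counts. Of 20 luminal genes, 7 rose and 1 fell, with 8 and 2 adjusted over the list alone. KRT7 rose by 0.91 (SE 0.16), the transcription factor ELF3 by 0.68 (SE 0.15), MUC1 by 0.67 (SE 0.13) and CDH1, E-cadherin, by 0.66 (SE 0.12). Of 12 basal and mesenchymal genes 1 rose, CDH3 or P-cadherin by 0.80 (SE 0.14), and of 3 measured fibroblast genes 1 rose, COL3A1, on 63 and 179 reads in MCF7 and 0 and 0 in T47D and under none of the 3 other scalings. Both counts were the same adjusted over the list alone. Of 7 measured genes of milk secretion, 3 rose and 1 fell, with 4 and 1 adjusted over the list alone: PLIN1 rose by 2.99 (SE 0.71) on at most 22 reads, ELF5 by 0.66 (SE 0.16) and PIP by 1.82 (SE 0.20), from 5854 to 20605 reads in T47D with 1 and 0 in MCF7, and PLIN2 fell by 0.87 (SE 0.25) but not with DESeq2 size factors or upper-quartile factors.

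**Figure D4:**
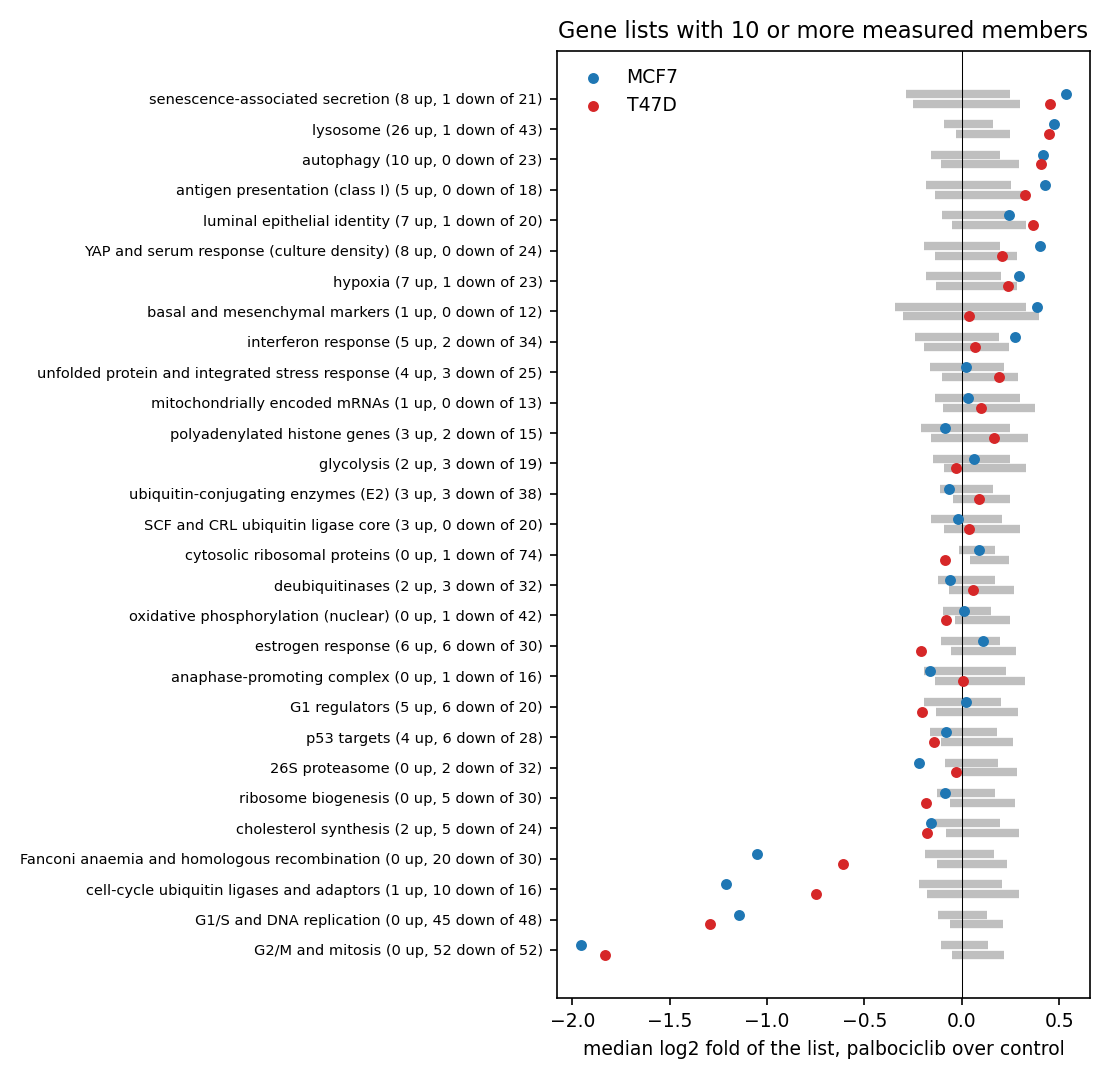
Median log2 fold of palbociclib over control in MCF7 (blue) and T47D (red) for each gene list with at least 10 measured members, with 1 library per condition in each line. Grey bars span 2 SD on each side of the median of 10000 random lists of the same size and expression, and the G2/M list lies at -1.95 and -1.83 and the lysosome list at 0.47 and 0.45.

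Within MCF7, 756 genes were higher and 912 lower by at least 2-fold in the palbociclib library. The highest were LRRC15 with a log2 fold of 3.11 (95% counting interval 2.55 to 3.99), CYP1A1 with 3.06 (2.85 to 3.30), CLEC3A with 2.96 (2.80 to 3.14), the integrin subunit ITGB6 with 2.67 (2.29 to 3.16) and the lipase LIPH with 2.55 (2.11 to 3.17). The lowest were CXCL8 with -3.46 (-4.50 to -2.87), PIF1 with -3.37 (-4.16 to -2.86), CDCA7 with -3.23 (-4.10 to -2.69), E2F7 with -2.90 (-3.26 to -2.62) and PTTG1 with -2.77 (-3.09 to -2.51). In T47D, ITGB6 had 15 and 15 reads and CDCA7 0 and 2. The comparison has 1 library against 1 and no replicate check.

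Within T47D, 882 genes were higher and 898 lower by at least 2-fold in the palbociclib library. The highest were CYP1A1 with a log2 fold of 3.87 (3.60 to 4.20), the cold-sensing channel TRPM8 with 3.70 (3.15 to 4.61), ANK1 with 3.02 (2.48 to 3.86), the serpin SERPINI1 with 2.93 (2.73 to 3.16) and TGFB2 with 2.61 (2.14 to 3.27). The lowest were PIF1 with -4.03 (-5.05 to -3.45), AURKB with -3.97 (-4.60 to -3.54), NEURL1B with -3.76 (-4.03 to -3.54), E2F7 with -3.75 (-4.28 to -3.37) and the DNA glycosylase NEIL3 with -3.73 (-4.50 to -3.24). In MCF7, TRPM8 had 0 reads in the control and 8 with palbociclib, at least 2.52-fold higher against a floor of 3 counts, with a log2 counting interval from 0.69 up. ANK1 and SERPINI1 passed the test across both lines although their MCF7 folds were -0.16 and -0.18, and ANK1 passed under none of the 3 other scalings. Neither passed with the robust option or in the DESeq2 Wald test, where SERPINI1 had 1.475 against 2.496 in edgeR. The difference between the lines was not tested, and with total counts in place of TMM 33.2% of the genes past 2-fold were higher, against 49.6%.

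The responses of the 2 lines were compared across genes. Of the genes past 2-fold, 241 were higher in both lines, where 40.1 would be shared by independent lists, and 354 were lower in both, against 49.2. In opposite directions were 24 genes higher in MCF7 and lower in T47D, against 40.8, and 22 the other way, against 48.3. GJC1, a gap junction protein, was higher in MCF7, at least 2.2-fold against that floor on 0 and 7 reads with a log2 counting interval from 0.44 up, and lower in T47D, with a log2 fold of -1.96. The potassium channel KCNK5 had 1.13 and -1.31, DHRS2 had 2.21 and -1.13, and TGFBR2 had 1.07 in MCF7 and in T47D 4 and 0 reads, with a log2 counting interval up to 0.63, which includes no change. NPR3, a natriuretic peptide receptor, had -1.55 and 1.55, ZNF608 had -1.78 and 1.13, KCNC1 had -1.65 and 1.12 and PCDHGB2 had -1.73 and 1.08. Pearson's r of the log2 folds was 0.495 and Spearman's rho 0.479 over 16641 genes, which are not independent replicates. Each line had its own control, and the lines differ in their medium.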

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

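In 8 of the named genes the lines went in opposite directions, with counting intervals on different sides of 0 in MCF7 and T47D. All except PGR were named because their lines went in opposite directions, so that outcome follows from the choice. Among all tested genes past 2-fold, 24 were higher in MCF7 and lower in T47D, against 40.8 for independent lists. The other way went 22, against 48.3. Each difference below is the MCF7 log2 fold minus the T47D log2 fold. It was not tested in any of the 8 genes, since each line has 1 library per condition. DHRS2 differed by 3.34, GJC1 by at least 3.09 against the floor and the potassium channel KCNK5 by 2.44. All were higher with palbociclib in MCF7 and lower in T47D. The MCF7 value of GJC1 rests on 0 and 7 reads and was taken against the floor of 3 counts. Its log2 counting interval in MCF7 runs from 0.44 up, which allows a difference smaller than 3.09. The difference was -3.10 for NPR3, -2.91 for ZNF608, -2.81 for PCDHGB2 and -2.76 for KCNC1, which were lower in MCF7 and higher in T47D. ZNF608 had 8 and 1 reads in MCF7, KCNC1 had 16 and 4, and PCDHGB2 overlaps other genes of its cluster. PGR, the progesterone receptor, differed by -0.64, from 3992 to 2872 reads in MCF7 and from 26088 to 27144 in T47D. Its T47D log2 fold of 0.09 turned to -0.07 with total counts, -0.05 in the authors' TPM and -0.07 in their FPKM, so its direction there depends on the scaling.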

How the results depend on the processing

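The alternative without lymphocyte genes was chosen after the data were seen. UBE2C ran from -2.16 to -2.02 across 11 other settings, UBE2S from -1.76 to -1.59 and UBE2T from -1.96 to -1.81, and all 3 passed in each setting except without the line block. There they had -2.05, -1.59 and -1.86 and an adjusted p of 1, 0 genes rose and 0 fell in edgeR (329 at an unadjusted p under 0.05), and the spread between lines enters the error by construction. With 1 line left out no residual degrees of freedom remain, so only values can be given. Of 298 such values of named genes, 127 lay within 1 SE of the fold across both lines, 164 lay further off and 7, all of called genes, had the opposite sign. Values of genes that were not called, such as KCNK5, DHRS2, NPR3 and PGR, also changed sign and are counted among the 127 and 164. FBXO5 ranged from -3.56 to -1.89, MYBL2 from -3.73 to -2.11, RRM2 from -3.65 to -2.15 and UBE2J1 from 0.33 to 0.90. UBE2S ranged from -1.86 to -1.44, CXCL8 from -3.46 to 0.0174, CDCA7 from -3.23 to 1.01, ANK1 from -0.16 to 3.02, SERPINI1 from -0.18 to 2.93, GJC1 from -1.96 to 2.13, ANKRD1 from -0.47 to 2.37 and PIP from -0.60 to 1.84. Of these ends, 0.0174, 1.01, 2.13, -0.47 and -0.60 rest on at most 7 reads in a library and on the prior count.

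The 1500 genes that rose became 983 with upper-quartile factors and 906 with total counts, where 1373 fell in place of 1015. DESeq2's Wald test called 958 up and 529 down, 1455 of these calls also made by edgeR, and gave GJC1 a log2 fold of 1.43, the opposite of edgeR. limma on the authors' normalized values called 230 up and 422 down (35.3% up). Total counts moved the median of all genes in T47D by -0.13 and the authors' TPM by -0.10, and other settings moved it by less than 0.1 in each line. Some called genes had no adjusted p in a setting, so whether their calls hold there is unknown. These include CXCL8 in DESeq2's Wald test, and CXCL8, LRRC15, CDCA7, TRPM8, SERPINI1 and GJC1 in limma. Of the named genes with an adjusted p, 27 lost the call in DESeq2's Wald test and 116 kept their side of the threshold. In limma 52 lost the call and 78 kept their side, and 12 lost the call with the robust option. These 12 were MKI67, RRM2, MYBL2, ITGB6, ANK1, SERPINI1, NEURL1B, GJC1, STARD4, TP53I3, PFKP and MT-CO1. The 27 were CDK4, ITGB6, CDCA7, ANK1, SERPINI1, UBE2E2, PSMB6, USP13, USP20, MCOLN1, STARD4, EBP, PSAT1, H4C8, TP53I3, INHBA, SAMD9, HLA-F, COL3A1, PLIN2, PIP, PFKP, SLC16A3, COX8A, RPS10, DKC1 and NOP56. The 52 were CDK4, ESR1, CLEC3A, ITGB6, ANK1, TGFB2, UBE2H, UBE2J1, UBE2E2, BTRC, FBXW11, DDB1, PSMC3, PSMB6, USP13, USP20, USP9X, MCOLN1, GNS, MAP1LC3B, ULK1, STARD4, EBP, TM7SF2, NDRG1, EGLN3, H1-0, H2BC4, H3-3B, H4C8, KCNK15, IGFBP5, AEN, TP53I3, SAMD9, HLA-F, ERAP1, TAPBP, ELF3, MUC1, CDH1, CDH3, PLIN2, ELF5, PFKP, SLC2A1, SLC16A3, COX8A, DKC1, NOP56, MT-CO1 and G6PD. USP20 was also lost without a filter, COL3A1 and MT-CO1 with protein-coding genes only and MT-CO1 without lymphocyte genes. LRRC15, CXCL8 and TRPM8, among others, lie below a mean of 5 CPM and have no value in that setting. At a mean of at least 5 CPM, 9 were lost: GJC1, UBE2E2, DDB1, USP13, USP20, STARD4, HLA-F, NOP56 and MT-CO1. The cause was not tested for any of these.

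Within MCF7, 756 higher and 912 lower became 1831 and 2979 with no filter and 310 and 424 at a mean of at least 5 CPM, where fewer genes enter. They became 243 and 326 in the authors' normalized values, 143 and 332 in FPKM, 319 higher in TPM, and 456 and 532 with a counting interval beyond 1.5-fold. Within T47D, 882 and 898 became 2625 and 2715 with no filter, 343 and 461 at a mean of at least 5 CPM, 259 and 381 in the authors' normalized values, 138 and 398 in FPKM, 334 higher in TPM, and 524 and 577 with that interval. The share that was higher, 45.3% in MCF7, was 32.6% in TPM and 30.1% in FPKM, and in T47D it was 49.6%, against 33.2% with total counts, 31.8% in TPM and 25.8% in FPKM. The T47D share was also 39.8% with TMM within the line, 40.5% in the authors' normalized values and 41.4% with upper-quartile factors. With DESeq2 size factors it was 49.5%. TPM and FPKM values carry a pseudocount, which shrinks folds of low genes.

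Pearson's r of the lines, 0.495, was 0.632 at a mean of at least 5 CPM and 0.244 with no filter, and rho was 0.587 and 0.238. At a mean of at least 5 CPM, 112 genes were higher in both lines, 9 were higher in MCF7 and lower in T47D and 4 went the other way. With no filter, 385 were higher and 630 lower in both, and 122 and 195 went in opposite directions. Of 272 counts of list members called, 43 moved by over 1.5 times, and of 338 list medians 82 moved by over 1 SD of matched random lists. Of 1602 values of named genes across both lines with a test, 1310 kept their side of the threshold, 282 lost the call and 9 gained it. In 1 value, GJC1 in DESeq2's Wald test, the sign was reversed. Of the 282 losses, 138 came from leaving out the line block, where no gene passed. Depth limits genes near the floor of 3 counts, such as TRPM8 and GJC1 in MCF7 and INHBA and CDCA7 in T47D.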

Other observations

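All tests in this part were chosen after the result was seen, except that of gene length with GC content for the lysosome and autophagy lists.

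Genes outside the lists moved as well, and those named here were picked after their values were seen. LMNB1, the nuclear lamin B1, fell by 2.32 (SE 0.14), STMN1, a regulator of microtubules, fell by 2.02 (SE 0.14) and EZH2, the methyltransferase of the Polycomb complex, fell by 1.72 (SE 0.18), each lower in 2 of 2 lines. VTCN1, the immune checkpoint ligand B7-H4, rose by 2.16 (SE 0.18), EDN1, endothelin 1, by 1.72 (SE 0.17), AKR1C3 by 1.76 (SE 0.19), EPAS1, which encodes the hypoxia factor HIF-2 alpha, by 1.43 (SE 0.14) and TXNIP, a thioredoxin inhibitor, by 1.26 (SE 0.14). Their adjusted p-values in edgeR ran from 5.8e-11 for LMNB1 to 4.1e-07 for TXNIP.

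Of 18 listed and measured targets of NRF2, the transcription factor of the oxidative stress response, 11 rose, 0 fell and 7 did not pass, with 11 and 0 adjusted over the list alone. NQO1 rose by 1.18 (SE 0.12), G6PD, the entry enzyme of the pentose phosphate pathway, by 1.06 (SE 0.15), TXNRD1, thioredoxin reductase, by 1.05 (SE 0.13) and OSGIN1 by 0.87 (SE 0.14).

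The rise of CYP1A1 was weighed against 3 explanations. If it were part of a general rise of aryl hydrocarbon receptor targets, the other 8 measured targets should lie above the central 95% of matched lists in each line; their median of 0.49 in MCF7 lay at 99.3 and that of 0.35 in T47D at 91.9, with 3 up and 0 down, and 4 and 1 adjusted over the list alone. This stays open, because 1 line lies on each side of that bound. CYP1B1 rose by 1.14 and ALDH3A1 by 2.26, the latter with 2.33 in MCF7 and 0.60 in T47D. CYP2S1, the member down adjusted over the list alone, had -0.63 in MCF7 and -1.03 in T47D, and SLC7A5 had -0.30 and 0.11. The NRF2 targets, 1 of which (NQO1) is also on the receptor list, had medians of 0.58 and 0.45 at percentiles 100 and 99.9, but because that list was written after values of its genes were seen, this does not support an oxidative stress response, which stays open. Days in culture instead of the drug cannot be told apart from it, because there were 0 control libraries of day 5.

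The medians above 0 of the lysosome and autophagy lists were weighed next, over 66 pooled genes. After the trend of the folds on gene length and GC content was removed, the pooled medians were 0.46 in MCF7 and 0.37 in T47D, and the lower of the 2 percentiles among matched lists was 100, which argues against that trend as the whole cause. Under DESeq2 size factors, upper-quartile factors and total counts the pooled median was at least 0.29 in each line. That is above 0.106, which is 2 SD of matched lists, so the median stayed above 0 under each of these scalings. A scaling moves the folds of a line by about the same amount, and total counts moved the T47D median of all genes by only -0.13. The outcome follows from that small shift, so no conclusion is drawn on other errors of scaling. The test planned before took away the median of all genes, which fixes its outcome, and was dropped. Days in culture instead of the drug stay open, with 0 control libraries of day 5, and cannot be told apart from the drug. A lysosomal response to palbociclib is a hypothesis that these 4 libraries leave untested.

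The reads of lymphocyte genes were weighed last, from lists of markers of which 4 genes (CD3D, CD3E, MS4A1 and PTPRC) had been listed before. Whole lymphocytes or their full RNA should bring the pan-leukocyte genes, yet the median count of 17 such genes over the PTPRC count reached at most 0.0323; CD53, LAPTM5 and IL2RG had at most 7 reads, although ITGB2, SELL, CXCR4 and CCR7 had between 297 and 4172. Expression by the breast lines themselves should differ between lines as other genes do, yet the SD of the MCF7 to T47D control ratio was 0.0489 times that of all genes of that level. A single outside source of reads of selected lymphocyte genes, added to each library, may account for the pattern. The SD of the log2 ratio over the listed genes was at most 0.105 in any pair of libraries. That nearly fixed ratio is the pattern itself, so it cannot serve as separate support for such a source. The design gives no biological explanation to test, and what the source was cannot be read from counts.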
